A study of Homo sapiens with 18 samples.

How the data were processed

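RNA sequencing measured gene expression in 18 cultures of the breast cancer lines MCF-7 and LCC9, 3 for each of 6 groups formed by line and transfected oligonucleotide. Per the labels, cells were grown in phenol red IMEM with charcoal-stripped serum and transfected for 48 h with anti-miR-29a, pre-miR-29a or pre-miR-29b-1. The labels also state that anti-miR-29a blocks both miR-29a and miR-29b-1, that the transfections were made in separate experiments, and that microRNA levels were checked by quantitative PCR. Those PCR values are not part of the deposited table. Per the labels' protocols, the libraries were stranded, prepared from mRNA and sequenced as single reads. Per the submitters' processing notes, FastQC, TopHat2, Bowtie2, Cuffdiff 2.2.1 and Cuffnorm were used with the GRCh37 (hg19) genome. The notes give neither the roles of the tools, nor the annotation release, nor whether Cuffnorm rescaled the libraries.

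The authors deposited 1 table of FPKM (fragments per kilobase of transcript per 1e6 mapped reads) with 62545 Ensembl genes and 1 column per library. The deposited FPKM were taken as given, 1 was added, and the log2 was computed from them. All 18 columns were used. A gene symbol was found for 42930 of the 62545 identifiers, and for 14762 of the 16835 genes tested. Read counts were not used here. Of 7864 low genes, 4041 (51.4%) had every FPKM value within 2% of a whole multiple of their smallest, and these steps were taken as 1 read. The step heights gave the depth of each library relative to the deepest, from 0.42 to 1. With transcript lengths from GENCODE release 44 lifted to GRCh37, they put the depth at 25.9 to 61.7 times 1e6 reads. The estimate is the most frequent value over 1239 genes. For the deepest library it lies just above the upper quartile of these genes (quartiles of 49.5 and 61.6 in the same unit), so the absolute depths are approximate. The size of a step covers counting error only.

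Genes with at least 1 FPKM in at least 3 libraries were tested, 16835 in all. One linear model with a mean per group was fitted to the 18 libraries with limma 3.58.1 (R 4.3.3), with a mean-variance trend, 12 residual and 2.26 prior degrees of freedom. Tests were two-sided. The p-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. In each line both precursors were compared with anti-miR-29a and with each other. LCC9 was compared with MCF-7 as the mean of the differences at matched transfection. The interactions test whether a precursor's difference from anti-miR-29a differs between the lines. The p-values measure variation among 3 cultures per group of 1 stock of each line. A log2 difference is the difference of group means of log2(FPKM + 1), which understates the change of genes near or below 1 FPKM. Its standard error (SE) comes from limma, while FPKM are given as mean ± SD over the 3 libraries of a group.

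Gene lists were tested with camera in limma, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. Of 26 lists written, the 20 with at least 5 tested members entered. They cover miR-29 targets of the matrix, of DNA methylation and other miR-29 targets, oxidative phosphorylation, glycolysis, cholesterol synthesis, estrogen response, luminal identity, growth factor receptors, mesenchymal and basal genes, proliferation, replication histones, interferon response, unfolded protein response, p53 targets, the BCL2 family, microRNA machinery, hypoxia, ribosomal proteins and immediate early genes. For each list, members past the threshold over all genes are given beside the number adjusted over the list alone. Lists of fibroblast, leukocyte and endothelial markers, mitochondrial transcripts, miR-29 loci and ATP synthase genes picked for this study were too small after the filter.

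The seed shared by miR-29a and miR-29b pairs with TGGTGCT and GGTGCTA, and TGGTGCTA gives the longer 8mer match. These sites were searched in the longest annotated 3′ UTR of each gene, which 12393 of the 16835 genes had (73.6%; 12391 of 12427 protein-coding genes). The difference in median log2 difference between genes with a site and genes without its 6-base core was set beside 100 random 7-mers of the same base composition. The share of genes with a site among called genes was compared with that among all other searched genes by Fisher's exact test. Genes are not independent replicates in either calculation. Agreement between comparisons that share libraries was set beside 20 simulations with no effect.

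The tests, lists, other settings and the rule for genes named in the text were fixed before the data were examined. The rule takes, per comparison, the 8 highest and 8 lowest genes by log2 difference among those past the threshold, with separated replicates and a mean of at least 5 FPKM in the higher group. It takes 3 per direction for precursor against precursor and for the interactions, where replicates need not be separated. Clones, small RNAs and blank names are passed over. It adds 19 fixed genes in every comparison, and the list members with the smallest adjusted p. How many of those members are printed was decided after their values were seen, and levels of XIST and Y-linked genes were left out. The other settings fixed then were another scaling (median ratio or quantile), another value added before the log2 (0.1 or 5), no filter or a minimum of 5 FPKM, a robust fit, only the groups compared, each library left out in turn, a replicate block, and a log2 size of at least 1. For the lists they were the estimated correlation, fry, the replicate block, the minimum of 5 FPKM and 0.1 added before the log2, and for seed sites single site types and each library left out. Removal of a GC and length trend (a spline with 4 degrees of freedom per library), the omission of pairs of libraries, and the list tests under other scalings and with each library left out were added after the data were seen.

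The fits were tested on simulated data built from these libraries. For the limma shares, genes were planted only among those with a mean log2(FPKM + 1) above 2. The simulated noise was independent between genes. The shares therefore do not cover lower genes or errors that genes share within a library. For pre-miR-29a against anti-miR-29a in MCF-7, limma over 16835 genes recovered 44.8% of planted genes at a log2 size of 0.5, 88.1% at 1 and 100% at 2, and 3.1% of its calls were false. In LCC9 the same comparison recovered 52.2%, 83.6% and 97% at these sizes, with 6.1% false calls. For the interactions the shares were 19.4%, 76.1% and 95.5% with pre-miR-29a and 7.5%, 71.6% and 95.5% with pre-miR-29b-1. Camera recovered a planted list of 24 genes in the MCF-7 comparison. A planted seed effect of -0.1 there was measured as -0.0976. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 did the remaining work.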

Results

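Messenger RNA was sequenced from 18 cultures of human breast cancer cells. MCF-7 is an estrogen receptor-positive line sensitive to tamoxifen, and LCC9 is an antiestrogen-resistant line derived from it. Each line was transfected for 48 h with an inhibitor of miR-29a (anti-miR-29a), the precursor of miR-29a (pre-miR-29a) or the precursor of miR-29b-1 (pre-miR-29b-1), with 3 libraries per group. No group received a neutral control, so a difference can come from the precursor, from the inhibitor or from both. The estimated depth in units of 1e6 reads ran from 25.9 to 43.8 in MCF-7 and from 31.1 to 61.7 in LCC9. Between 14172 and 15018 genes per library reached 1 FPKM. Across genes, the log2 profiles of libraries of a group correlated at 0.962 to 0.982 (Pearson's r; genes are not independent replicates). The first principal component held 62.6% of the variance and separated LCC9 (-76.4 to -55.2) from MCF-7 (52.4 to 81.7). The second held 7.8% and separated the LCC9 anti-miR-29a libraries (-46.7 to -26.0) from the LCC9 precursor libraries (13.9 to 26.1). On it MCF-7 anti-miR-29a replicate 2 (-31.75) stood apart from replicates 1 and 3 (-10.87 and -10.45). Its deviations from the group mean correlated with GC content at -0.745, those of replicates 1 and 3 at 0.621 and 0.7.

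Pre-miR-29a was compared with anti-miR-29a in MCF-7 to find transcripts that follow miR-29a in endocrine-sensitive cells. Interferon-stimulated genes were higher with the precursor, and miR-29 targets of the extracellular matrix were lower, as was TDG, a gene of DNA demethylation. XAF1, an interferon-induced regulator of apoptosis, rose from 4.61 ± 0.991 to 37.9 ± 2.23 FPKM (log2 difference 2.81, SE 0.15, limma adjusted p = 1.56e-07). IFNB1, which encodes interferon beta, rose from 1.29 ± 0.131 to 8.54 ± 0.633 FPKM (2.06, SE 0.16, limma adjusted p = 4.81e-06). KLHDC7B (2.80), IFIT3 (2.56), OAS2 (2.53), CMPK2 (2.46), MX2 (2.27) and PSMB9 (2.06) complete the 8 largest increases, with limma adjusted p from 1.12e-08 to 2.19e-05. Of 38 tested members of the interferon response list, 35 were higher (38 adjusted over the list alone), with a median of 1.27 (camera adjusted p = 2e-44; 0.0175 with an estimated correlation). IRF1, a transcription factor of that response, rose by 1.52 (limma adjusted p = 7.67e-07). Among 13 immediate early genes 10 were higher (11 adjusted over the list alone), with a median of 0.63 (camera adjusted p = 3.7e-10; 0.0455 with an estimated correlation), including ATF3 (0.97) and MYC (0.50).

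Among known miR-29 targets in the same MCF-7 comparison, 9 of 16 matrix genes were lower (10 adjusted over the list alone), with a median of -0.41 (camera adjusted p = 2.6e-07; 0.00592 with an estimated correlation). ITGB1, integrin beta 1, fell from 126 ± 14.3 to 81.3 ± 4.65 FPKM (-0.62, limma adjusted p = 8.86e-05). TDG (ENSG00000139372, chromosome 12, 104359600 to 104382652, GRCh37), the thymine DNA glycosylase of active demethylation, fell from 42.4 ± 4.72 to 24.5 ± 1.28 FPKM (-0.76, SE 0.08, limma adjusted p = 3.58e-05). DNMT3B (-0.45, 0.00136), TET1 (-0.61, 0.00549) and TET3 (-0.89, 0.00838) also passed limma's threshold (log2 difference, adjusted p). With them 4 of the 7 DNA methylation genes were lower (4 adjusted over the list alone), with a median of -0.45 (camera adjusted p = 2.67e-06; 0.0561 with an estimated correlation). Of 53 other targets 12 were lower and 4 higher (15 and 6 adjusted over the list alone), with a median of -0.15 (camera adjusted p = 1.48e-05; 0.0345 with an estimated correlation). CDK6, a cell cycle kinase, fell by 0.41 on the log2 scale (limma adjusted p = 0.00319). PPIC, with 1 8mer site in its 3′ UTR, fell from 71.8 ± 1.84 to 32.3 ± 0.698 FPKM (-1.13, limma adjusted p = 1.16e-05). The other large decreases were PGM5 (-1.48), PKP1 (-1.16), IGSF3 (-1.01), SESTD1 (-1.0), GRIP1 (-1.0), ALG14 (-0.97) and CAV1 (-0.94), with limma adjusted p from 1.16e-05 to 0.00965. SESTD1 and GRIP1 carry 8mer sites and PKP1 a 7-base site, while PGM5, IGSF3, ALG14 and CAV1 carry none.

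Smaller shifts in this comparison reached lists whose calls rest on the preset correlation. Estrogen response genes had a median of 0.24 with 5 of 40 higher and 1 lower (7 and 1 adjusted over the list alone; camera adjusted p = 0.0104, 0.149 with an estimated correlation). Their median was 0.12 with a GC and length trend removed. Glycolysis genes had a median of -0.11 with 2 of 19 lower and 1 higher (3 and 1 adjusted over the list alone; camera adjusted p = 0.00355, 0.0668 with an estimated correlation), among them ENO1 (-0.47). Oxidative phosphorylation genes had a median of -0.07 with 1 of 49 lower (1 adjusted over the list alone; camera adjusted p = 0.00497, 0.605 with an estimated correlation). Both of these calls ended under quantile normalization (0.32 for oxidative phosphorylation, 0.153 for glycolysis). Growth factor receptors had a median of -0.09 with 2 of 13 lower (2 adjusted over the list alone; camera adjusted p = 0.0224, 0.353 with an estimated correlation), and 0.0598 without pre-miR-29a replicate 3. The p53 targets had a median of 0.17 with 5 of 24 higher (5 adjusted over the list alone; camera adjusted p = 0.0483, 0.0979 with an estimated correlation), AEN (0.63) among them. Their adjusted p rose to 0.0521 and 0.0516 without anti-miR-29a replicate 1 or 3, and to 0.0561 and 0.0591 without pre-miR-29a replicate 1 or 3. TET2, DNMT3A, MCL1, PIK3R1, ATP5MC1, ATP5IF1, ESR1, PGR, GREB1, TFF1, ERBB2 and EGFR missed the threshold, with limma adjusted p from 0.225 (TET2) to 0.977 (ATP5MC1). COL4A1 and COL4A2 lay below the expression filter in all comparisons.

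In all, 1392 genes passed limma's threshold in this comparison, 804 higher and 588 lower, and 106 and 14 of them differed by at least 1 on the log2 scale. Omitting pre-miR-29a replicate 1 or 3 left 761 or 749 genes, a fit of only these groups gave 491, and removal of a GC and length trend gave 2211, 982 higher and 1229 lower. Scaling by median ratio gave 601 higher and 995 lower genes, and quantile normalization 537 and 862, so the share of higher calls fell from 57.8% to 37.7% and 38.4%.

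**Figure D1:**
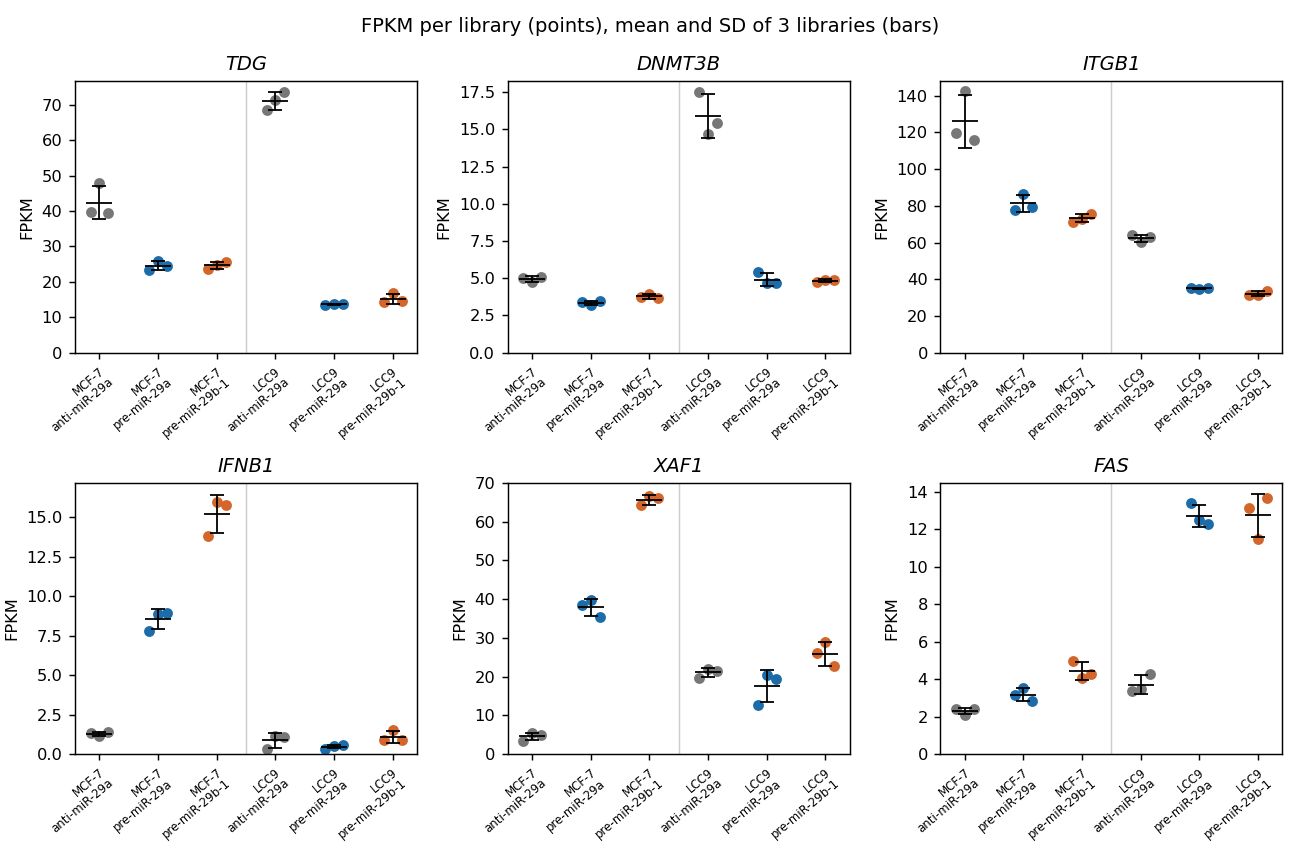
FPKM of TDG, DNMT3B, ITGB1, IFNB1, XAF1 and FAS in the 6 groups on a linear axis from 0; points are libraries, and bars give the mean and SD of 3. IFNB1 and XAF1 rise with both precursors in MCF-7, TDG and DNMT3B fall further in LCC9 than in MCF-7, and ITGB1 falls in both lines.

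MCF-7 cells with pre-miR-29b-1 were compared with anti-miR-29a to ask the same of the other microRNA of the cluster. Again interferon genes made up most of the largest increases, and miR-29 targets of the matrix were lower. XAF1 reached 65.6 ± 1.2 FPKM (3.59, SE 0.15, limma adjusted p = 7.75e-09) and IFNB1 15.2 ± 1.2 FPKM (2.82, limma adjusted p = 6.94e-08). IFNL2, an interferon lambda gene, rose from 0.885 ± 0.247 to 18 ± 5.71 FPKM (3.30, limma adjusted p = 6.05e-08). KLHDC7B (3.34), OAS2 (3.27), IFIT3 (3.22), CMPK2 (3.14) and PSMB9 (3.01) had limma adjusted p from 1.91e-09 to 8.96e-07. ISG15 rose by 3.43 with a wide spread among its libraries (SE 0.59, limma adjusted p = 0.00112). All 38 interferon response genes were higher (38 adjusted over the list alone), with a median of 1.80 (camera adjusted p = 1.15e-36; 0.0465 with an estimated correlation), IRF1 among them (1.93). Of 13 immediate early genes 12 were higher (12 adjusted over the list alone), with a median of 0.82 (camera adjusted p = 5.39e-09; 0.0866 with an estimated correlation), including MYC (0.70).

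In the matrix list 8 genes were lower and 1 higher (9 and 3 adjusted over the list alone), with a median of -0.40 (camera adjusted p = 0.000745; 0.0465 with an estimated correlation). ITGB1 fell to 73.3 ± 2.32 FPKM (-0.77, limma adjusted p = 6.56e-06), and ITGA6, integrin alpha 6, by 0.72 on the log2 scale (limma adjusted p = 0.00105). TDG (-0.75, 1.8e-05), DNMT3B (-0.32, 0.0069), TET1 (-0.64, 0.00185) and TET3 (-0.81, 0.00687) were lower (log2 difference, limma adjusted p). The DNA methylation list had 4 lower genes (5 adjusted over the list alone) and a median of -0.44 (camera adjusted p = 0.000593; 0.117 with an estimated correlation). The other targets had 14 lower and 6 higher genes (15 and 6 adjusted over the list alone) and a median of -0.12 (camera adjusted p = 0.00225; 0.117 with an estimated correlation). Its members ZFP36 (1.07) and VEGFA (0.73) rose (limma adjusted p = 9.49e-06 and 7e-06). PGM5 (-1.76), GRIP1 (-1.26), PPIC (-1.16), LTBP1 (-1.15), PKP1 (-1.12), SEMA3D (-1.10) and CAV1 (-1.07) had limma adjusted p from 3.01e-06 to 0.000943. CBX3P2, a pseudogene whose reads a parent gene can share, had the largest decrease (-3.97, SE 1.15, limma adjusted p = 0.0228). Its adjusted p was 0.0518 without anti-miR-29a replicate 1, 0.0683 without replicate 3, and 0.0593, 0.0543 and 0.0535 without pre-miR-29b-1 replicate 1, 2 or 3.

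Estrogen response genes had 12 higher and 2 lower of 40 (18 and 2 adjusted over the list alone) and a median of 0.32 (camera adjusted p = 0.00605; 0.117 with an estimated correlation). Their median was 0.21 with a GC and length trend removed. Oxidative phosphorylation genes had 7 lower (2 adjusted over the list alone) and a median of -0.10 (camera adjusted p = 0.00568; 0.604 with an estimated correlation). Glycolysis genes had 5 lower and 1 higher (7 and 1 adjusted over the list alone) and a median of -0.11 (camera adjusted p = 0.00622; 0.117 with an estimated correlation). Quantile normalization ended both of the latter calls (0.21 each). CDK6 fell by 0.25 on the log2 scale (limma adjusted p = 0.0257), a call lost without anti-miR-29a replicate 1 (0.0819) or 2 (0.063) and without pre-miR-29b-1 replicate 1 (0.0632) or 2 (0.0849), and with a GC and length trend removed (0.405). TFF1 missed the threshold (0.75, limma adjusted p = 0.053), and passed it without anti-miR-29a replicate 3 (1.02, 0.0129). TET2, DNMT3A, MCL1, PIK3R1, ATP5MC1, ATP5IF1, ESR1, PGR, GREB1, ERBB2 and EGFR also missed the threshold, with limma adjusted p from 0.0557 (TET2) to 0.969 (DNMT3A).

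The comparison gave 4033 genes past limma's threshold, 2604 higher and 1429 lower, of which 402 and 25 differed by at least 1 on the log2 scale. Without pre-miR-29b-1 replicate 1 there were 2322, without anti-miR-29a replicate 2 there were 2501, and without both 1729. A fit of only these groups gave 1472. With median-ratio scaling 1846 were higher and 2402 lower, with quantile normalization 1689 and 2563, and the share of higher calls fell from 64.6% to 43.5% and 39.7%. Quantile normalization moved the median log2 difference of all genes from 0.06 to -0.05.

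LCC9 cells with pre-miR-29a were compared with anti-miR-29a to find the transcripts that follow miR-29a in endocrine-resistant cells. Targets of the p53 pathway were higher, while TDG and DNMT3B were lower. KLF2, a Krüppel-like transcription factor, rose from 0.741 ± 0.309 to 11.2 ± 1.17 FPKM (2.82, SE 0.13, limma adjusted p = 2.41e-09). HMOX1, heme oxygenase 1, rose from 10.9 ± 1.68 to 46.1 ± 8.58 FPKM (1.97, limma adjusted p = 2.9e-07). KLF6 (2.08), PALM3 (1.99), ANXA3 (1.97), TUBB3 (1.91) and GPRC5A (1.78) had limma adjusted p from 2.15e-09 to 4.58e-05, and SLC2A3P1, a pseudogene, rose by 1.92 (0.00444). Of 24 p53 targets 16 were higher and 1 lower (16 and 1 adjusted over the list alone), with a median of 0.50 (camera adjusted p = 3.49e-07; 0.00158 with an estimated correlation). FAS, the death receptor, rose from 3.72 ± 0.501 to 12.7 ± 0.59 FPKM (1.54, limma adjusted p = 3.52e-08) and TP53INP1 by 1.20 (9.09e-07). PPM1D, a p53 target that miR-29 also targets, was the member that fell (-0.84, limma adjusted p = 8.32e-07).

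TDG fell from 71.2 ± 2.54 to 13.7 ± 0.151 FPKM in LCC9 (-2.30, SE 0.08, limma adjusted p = 1.56e-10), and DNMT3B from 15.9 ± 1.47 to 4.9 ± 0.426 FPKM (-1.52, SE 0.07, limma adjusted p = 3.08e-09). TET1 (-0.69, 0.000348), TET2 (-0.60, 0.00697) and TET3 (-0.74, 0.0053) were lower (log2 difference, limma adjusted p). In the DNA methylation list 5 genes were lower (5 adjusted over the list alone), with a median of -0.69 (camera adjusted p = 0.002; 0.279 with an estimated correlation). The anti-miR-29a libraries differed in this list, with medians of 0.75, -0.23 and 0.05 against the mean of 18 libraries, where the pre-miR-29a libraries lay at -0.38 to -0.29. Without anti-miR-29a replicate 1 the median difference was -0.43. Other miR-29 targets had 22 lower and 9 higher of 53 (23 and 10 adjusted over the list alone), with a median of -0.21 (camera adjusted p = 0.00824; 0.279 with an estimated correlation, and 0.208 without anti-miR-29a replicate 1). INSIG1 (-1.71, 3.55e-10), MYBL2 (-2.13, 1.95e-07) and MCL1 (-0.55, 5.58e-05) were among them. Matrix targets had a median of -0.08 and missed the threshold (camera adjusted p = 0.252), with 4 of 16 lower (4 adjusted over the list alone). Within that list, SERPINH1, a collagen chaperone, fell from 158.7 ± 6.21 to 37.2 ± 2.16 FPKM (-2.06, limma adjusted p = 2.23e-07) and ITGB1 from 62.3 ± 1.94 to 35.1 ± 0.36 FPKM (-0.81, 9.77e-07). KIT, a receptor tyrosine kinase, fell by 1.20 on the log2 scale (limma adjusted p = 4.07e-07).

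The largest decreases were CCDC167 (-3.21, 87.0 ± 29.1 to 8.14 ± 0.342 FPKM), TIMM8B (-2.97), PDXP (-2.90), TBC1D7 (-2.72), PRMT6 (-2.69, 127 ± 10.3 to 18.9 ± 1.31 FPKM), RCC2-AS1 (-2.67), TAF11 (-2.55) and HPGD (-2.54). Their limma adjusted p ran from 1.3e-11 to 9.09e-06. RCC2-AS1 is antisense to another gene, and whether the counting used strand is not stated. TIMM8B and HPGD carry 1 8mer site each, CCDC167 1 and TAF11 2 7-base sites of the m8 type. PDXP, TBC1D7 and PRMT6 carry no site.

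Genes of oxidative phosphorylation had 37 lower of 49 (40 adjusted over the list alone) and a median of -0.52 (camera adjusted p = 2.64e-09; 0.534 with an estimated correlation), ATP5MC3 (-0.99), ATP5MC1 (-0.82, limma adjusted p = 0.000292) and ATP5IF1 (-0.79, 0.00075) among them. Ribosomal protein genes had 16 lower of 24 (20 adjusted over the list alone) and a median of -0.60 (camera adjusted p = 1.2e-05; 0.534 with an estimated correlation), RPS29 (-1.24) among them. The anti-miR-29a libraries differed in both lists, with medians of 0.22, 0.91 and 0.74 for oxidative phosphorylation and 0.10, 0.86 and 0.63 for ribosomal proteins, against the mean of 18 libraries. Deviations of anti-miR-29a replicates 1, 2 and 3 from their group mean correlated with log2 transcript length at 0.56, -0.583 and -0.265. The median transcript length was 1832 and 1524.5 bases in these lists, against 3143.5 over all genes tested. Without replicates 2 and 3 the median differences were -0.11 and -0.20. Estrogen response genes had 19 lower and 7 higher (20 and 7 adjusted over the list alone) and a median of -0.24 (camera adjusted p = 0.0173; 0.279 with an estimated correlation, and 0.154 without anti-miR-29a replicate 1). CXCL12 (-1.48, 2.43e-10), SIAH2 (-1.91) and TFF1 (-1.06, 0.00534) fell, TFF1 from 1711 ± 325 to 810.2 ± 69.7 FPKM. Interferon response genes had 18 lower and 3 higher of 38 (18 and 4 adjusted over the list alone) and a median of -0.42 (camera adjusted p = 0.00407; 0.71 with an estimated correlation, and 0.0535 without pre-miR-29a replicate 1). IFI44 fell by 1.75 on the log2 scale. Cholesterol synthesis genes had 9 lower and 3 higher of 24 (12 and 3 adjusted over the list alone) and a median of -0.29 (camera adjusted p = 0.0273; 0.279 with an estimated correlation, and 0.0535 without pre-miR-29a replicate 1).

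ESR1, the estrogen receptor gene, rose by 0.61 (limma adjusted p = 0.00361) and ERBB2 by 0.71 (0.00469). Without anti-miR-29a replicates 2 and 3, ESR1 (0.46, 0.149), ERBB2 (0.38, 0.279), TFF1 (-0.76, 0.196), ATP5IF1 (-0.45, 0.0674) and SLC2A3P1 (0.45, 0.481) missed the threshold. DNMT3A, CDK6, PIK3R1, PGR, GREB1 and EGFR missed the threshold, with limma adjusted p from 0.123 (PIK3R1) to 0.943 (GREB1). Without anti-miR-29a replicate 1, PIK3R1 rose by 1.01 (1.92e-05) and GREB1 by 0.21 (0.0278). The count past limma's threshold was 6881 genes, 3297 higher and 3584 lower, of which 315 and 440 differed by at least 1 on the log2 scale. Without anti-miR-29a replicates 2 and 3 it was 3549, with 1903 higher and 1646 lower.

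In LCC9, pre-miR-29b-1 was also compared with anti-miR-29a. The p53 targets again rose, and TDG and DNMT3B fell. KLF2 reached 16.8 ± 0.683 FPKM (3.37, SE 0.13, limma adjusted p = 4e-10), and TUBB3 (2.11), HMOX1 (2.10), PHLDA3 (2.06), KLF6 (2.02), GDF15 (1.97) and PALM3 (1.92) rose with limma adjusted p from 2.82e-09 to 0.000155. RPL39P34, a ribosomal protein pseudogene, rose by 2.48 (SE 0.61, limma adjusted p = 0.00543). Of the p53 targets 17 were higher and 1 lower (17 and 1 adjusted over the list alone), with a median of 0.59 (camera adjusted p = 4.87e-08; 0.000765 with an estimated correlation). FAS (1.54, 3.63e-08) and DDB2, a DNA damage binding protein (1.01, 6.47e-07), rose, and PPM1D fell (-0.76, 2.28e-06; log2 difference, limma adjusted p). Immediate early genes had 7 higher and 2 lower of 13 (7 and 2 adjusted over the list alone) and a median of 0.44 (camera adjusted p = 0.049; 0.608 with an estimated correlation), with JUN at 1.82. That call ended without anti-miR-29a replicate 1, 2 or 3 (0.107, 0.0531 and 0.0584) and without pre-miR-29b-1 replicate 3 (0.0649).

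TDG fell to 15.2 ± 1.39 FPKM (-2.16, limma adjusted p = 2.73e-10) and DNMT3B to 4.83 ± 0.0933 FPKM (-1.53, 2.82e-09), with TET1 (-0.78, 0.000154), TET2 (-0.69, 0.00334) and TET3 (-0.73, 0.00685) also lower. The DNA methylation list had 5 lower genes (5 adjusted over the list alone) and a median of -0.73 (camera adjusted p = 4.59e-05; 0.104 with an estimated correlation), and of -0.45 without anti-miR-29a replicate 1. Other targets had 22 lower and 10 higher (23 and 10 adjusted over the list alone) and a median of -0.21 (camera adjusted p = 0.000283; 0.0671 with an estimated correlation, and 0.0691 without anti-miR-29a replicate 1). INSIG1 (-1.75, 2.98e-10), MYBL2 (-1.97, 4.5e-07) and MCL1 (-0.47, 0.000283) fell. Matrix targets had 4 lower (4 adjusted over the list alone) and a median of -0.20 (camera adjusted p = 0.0445; 0.17 with an estimated correlation). Their adjusted p was 0.291 without anti-miR-29a replicate 1 and 0.0649 without pre-miR-29b-1 replicate 3. SERPINH1 (-1.91, 5.14e-07) and ITGB1 (-0.93, 3e-07) were lower (log2 difference, limma adjusted p).

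CCDC167 (-3.16), HPGD (-2.80), TIMM8B (-2.66), IL24 (-2.59), RCC2-AS1 (-2.51), VWC2L (-2.44), PRMT6 (-2.43) and TBC1D7 (-2.43) were the largest decreases, with limma adjusted p from 5.01e-11 to 3.64e-06. Estrogen response genes had 20 lower and 6 higher (23 and 7 adjusted over the list alone) and a median of -0.33 (camera adjusted p = 0.000187; 0.0671 with an estimated correlation), with CXCL12 at -1.60, SIAH2 at -1.79 and TFF1 at -1.08 (limma adjusted p = 0.00563 for TFF1). Cholesterol synthesis genes had 11 lower and 2 higher (11 and 2 adjusted over the list alone) and a median of -0.28 (camera adjusted p = 0.000983; 0.0671 with an estimated correlation). Oxidative phosphorylation genes had 24 lower (30 adjusted over the list alone) and a median of -0.36 (camera adjusted p = 5.6e-08; 0.53 with an estimated correlation), with ATP5MC1 at -0.61 (limma adjusted p = 0.00297). Ribosomal protein genes had 14 lower (15 adjusted over the list alone) and a median of -0.50 (camera adjusted p = 1.55e-05; 0.53 with an estimated correlation), with RPS29 at -1.04. Interferon response genes had 6 higher and 4 lower (6 and 4 adjusted over the list alone) and a median of -0.04 (camera adjusted p = 0.924), with IRF9 at 0.80 and IRF1 at 0.60. Without anti-miR-29a replicates 2 and 3 the oxidative phosphorylation median was 0.01 (camera adjusted p = 0.393). ERBB2 rose by 0.69 (limma adjusted p = 0.00637), and by 0.36 (0.308) without the same replicates, where TFF1 (-0.78, 0.187) and ATP5MC1 (-0.21, 0.25) also missed the threshold. DNMT3A, CDK6, PIK3R1, ATP5IF1, ESR1, PGR, GREB1 and EGFR missed the threshold, with limma adjusted p from 0.0727 (ATP5IF1) to 0.802 (CDK6). Without anti-miR-29a replicate 1, PIK3R1 (0.65, 0.00085) and ATP5IF1 (-0.53, 0.00597) passed, and without replicate 2, PGR (-0.47, 0.018) and GREB1 (-0.35, 0.0421). In this comparison 5963 genes passed limma's threshold, 3085 higher and 2878 lower, and 259 and 314 differed by at least 1 on the log2 scale. Without anti-miR-29a replicates 2 and 3 there were 3486, 1938 higher and 1548 lower.

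**Figure D2:**
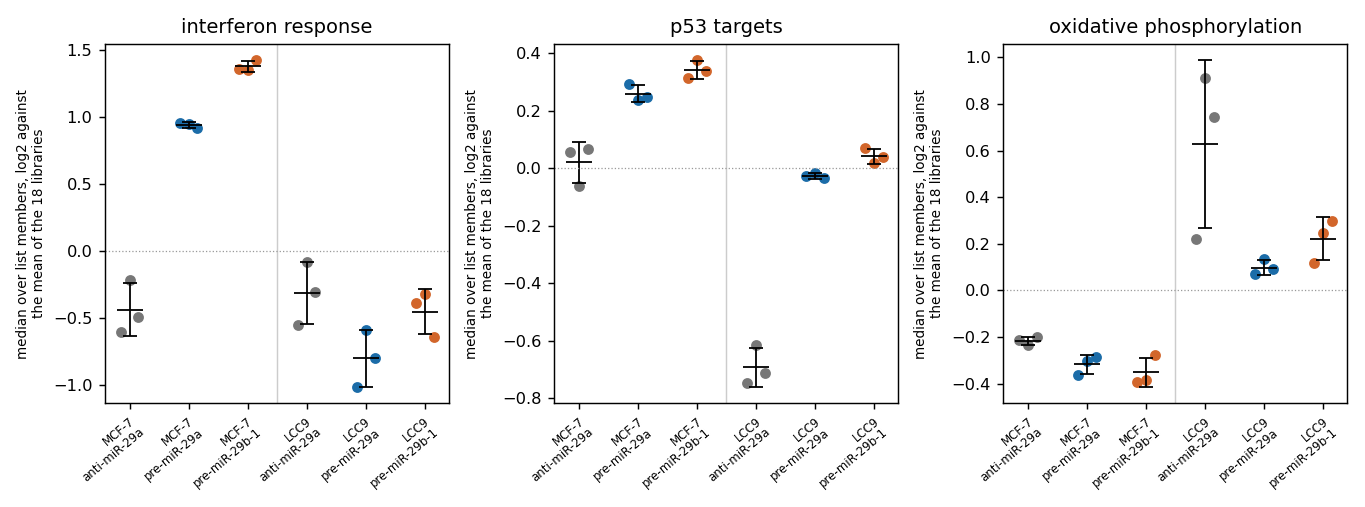
Median over the members of the interferon response, p53 target and oxidative phosphorylation lists in each library, as log2 against the mean of the 18 libraries; points are libraries, and bars give the mean and SD of 3 in each of the 6 groups. In MCF-7 the interferon response lies at -0.60 to -0.22 with anti-miR-29a and at 0.92 to 1.42 with the precursors, and in LCC9 the p53 targets lie at -0.75 to -0.62 with anti-miR-29a.

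Within a line, the 2 comparisons with anti-miR-29a called many of the same genes. In MCF-7, 733 genes were higher and 545 lower with both, and independent lists of these sizes would share 124.4 and 49.9. No gene past limma's threshold in both went opposite ways there (unadjusted p under 0.05 in 3712 and 6328 genes). In LCC9, 2525 genes were higher and 2625 lower with both (604.2 and 612.7 for independent lists), and 1 went opposite ways. The log2 differences correlated across genes at r = 0.71 in MCF-7 and 0.785 in LCC9, where shared anti-miR-29a libraries alone give 0.497 and 0.503 in 20 simulations with no effect. Their covariance was 0.121 against a simulated 0.0377 in MCF-7 and 0.221 against 0.0388 in LCC9. Neither the independent lists nor the simulations hold a real difference of the shared anti-miR-29a libraries. Such a difference enters both comparisons of a line alike. Part or all of the overlap and of the excess covariance may come from it. Between the lines, which share no libraries, r was 0.127 for pre-miR-29a and 0.219 for pre-miR-29b-1. For pre-miR-29b-1, 762 genes were higher and 559 lower in both lines (477.2 and 244.3 for independent lists), and 348 went opposite ways. For pre-miR-29a these counts were 272, 292 (157.5 and 125.2) and 175.

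The precursors were also set directly against each other, to ask whether microRNAs with 1 shared seed give different profiles. In MCF-7 IFNL2 and IFNL3, which encode interferon lambda, were lower with pre-miR-29a than with pre-miR-29b-1. IFNL3 had 1.92 FPKM with pre-miR-29a and 8.34 with pre-miR-29b-1 (-1.64, SE 0.23, limma adjusted p = 0.00998), and IFNL2 5.94 and 18 FPKM (-1.43, SE 0.18, limma adjusted p = 0.00615). LGALS9, galectin 9, was lower (-1.08) and LINC01291 higher (0.56), both with a limma adjusted p of 0.0355. These calls depend on single libraries: without pre-miR-29a replicate 3 the adjusted p was 0.0704 for IFNL3, 0.0515 for IFNL2, 0.212 for LGALS9 and 0.0919 for LINC01291. IFNL3 also missed the threshold without pre-miR-29a replicate 2 (0.0703), and LGALS9 and LINC01291 missed it without any 1 of the 6 libraries (0.0535 to 0.212 and 0.0757 to 0.23). In all 16 genes passed limma's threshold, 2 higher and 14 lower, with an unadjusted p under 0.05 in 1397. The count was 8 without pre-miR-29b-1 replicate 1 or 2 or pre-miR-29a replicate 2, 9 without pre-miR-29b-1 replicate 3, and 3 without pre-miR-29a replicate 3. It was 1 with 0.1 added before the log2, 44 with 5 added, 43 with no filter and 3 with a filter of 5 FPKM.

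Interferon response genes had a median of -0.42 between the MCF-7 precursor groups (camera adjusted p = 1.13e-20; 0.376 with an estimated correlation). CXCL10, a chemokine, was the member past limma's threshold (-0.70, adjusted p = 0.00615), and 24 members were lower when adjusted over the list alone. Immediate early genes had a median of -0.28 (camera adjusted p = 0.000121; 0.582 with an estimated correlation; 5 lower adjusted over the list alone). Replication histones had a median of -0.21 (camera adjusted p = 0.0097; 0.618 with an estimated correlation; 1 lower adjusted over the list alone), and 0.105 without pre-miR-29a replicate 2.

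In LCC9 2 genes separated the precursors, with an unadjusted p under 0.05 in 1406; they are named although they lie outside the rule, after their values were seen. MIR663AHG, a microRNA host transcript, had 0.259 ± 0.109 FPKM with pre-miR-29a and 15.1 ± 1.75 with pre-miR-29b-1 (-3.68, limma adjusted p = 1.01e-07). SNORD35A, a small nucleolar RNA, had 28.5, 49.5 and 6.58 FPKM in the pre-miR-29b-1 libraries and is listed at 0 in the 15 others. Without pre-miR-29a replicate 3, 10 genes passed. A fit of only these groups gave 653 genes, 67 higher and 586 lower, and there were 23 with no filter, 15 with 5 added before the log2, 4 with a replicate block and 5 with a GC and length trend removed. The interferon response list had a median of -0.40 (camera adjusted p = 2.93e-16; 0.334 with an estimated correlation; 16 lower adjusted over the list alone). Camera also called immediate early (-0.21, adjusted p = 0.00764; 1 lower adjusted over the list alone), oxidative phosphorylation (-0.13, 0.00764), cholesterol synthesis (0.07, 0.0083) and estrogen response genes (0.02, 0.0141). These calls ended with an estimated correlation (0.372, 0.664, 0.334 and 0.341). They also ended without pre-miR-29a replicate 1 (immediate early, 0.0622) or 3 (cholesterol synthesis, 0.0566; estrogen response, 0.0631) and without pre-miR-29b-1 replicate 3 (oxidative phosphorylation, 0.103). Among the fixed genes the lowest limma adjusted p between precursors was 0.599 in MCF-7 (CDK6) and 0.478 in LCC9 (ATP5IF1).

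LCC9 was compared with MCF-7 at matched transfection, to describe how the resistant line differs from its parent. Averaged over the transfections, most tested members of the proliferation and oxidative phosphorylation lists were higher in LCC9. Most of the interferon response, matrix target and unfolded protein response lists were lower, for the interferon response only with the precursors. None of these list calls held with an estimated correlation (adjusted p = 0.0929, 0.536, 0.474, 0.0929 and 0.179 in that order). FGFR4, a fibroblast growth factor receptor, had a mean of 176 FPKM in LCC9 and 2.6 in MCF-7 (5.64, SE 0.11, limma adjusted p = 2.38e-15), and PLS3, plastin 3, 147 and 0.311 (6.82, 8.1e-19). LINC01419 (7.60), TRGC1 (6.5), RAB34 (6.18), MEG3 (5.30) and CRISPLD1 (5.23) were higher in LCC9, and LINC01608 had a mean of 35.1 FPKM in LCC9 and is listed at 0 in the MCF-7 libraries. LGALS3, galectin 3, had 3.18 FPKM in LCC9 and 327 in MCF-7 (-6.34, limma adjusted p = 1.28e-18). LINC00052 (-7.46), AMIGO2 (-6.40), NR2F2 (-6.22), CA2 (-5.99), RAMP3 (-5.82) and SCUBE2 (-5.67) were lower in LCC9. All 36 proliferation genes were higher (36 adjusted over the list alone), with a median of 1.04 (camera adjusted p = 6.96e-10; 0.0929 with an estimated correlation), MCM7 (1.69) among them. Interferon response genes had 30 lower and 4 higher (30 and 6 adjusted over the list alone) and a median of -1.14 (camera adjusted p = 7.77e-06; 0.474 with an estimated correlation), with MX1 at -3.93 and STAT2 at -1.90. This difference depended on the transfection. Against the mean of 18 libraries, the list medians with anti-miR-29a were -0.55, -0.08 and -0.30 in LCC9. In MCF-7 they were -0.60, -0.22 and -0.49, so LCC9 did not lie lower there. With the precursors they were -1.01 to -0.32 in LCC9 and 0.92 to 1.42 in MCF-7.

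Oxidative phosphorylation genes had 38 higher and 3 lower in LCC9 (38 and 3 adjusted over the list alone) and a median of 0.59 (camera adjusted p = 0.000349; 0.536 with an estimated correlation), with ATP5F1A at 0.97. Matrix targets had 11 lower and 3 higher of 16 (11 and 3 adjusted over the list alone) and a median of -1.02 (camera adjusted p = 0.00553; 0.0929 with an estimated correlation), with COL5A1 at -3.0. Unfolded protein response genes had 18 lower and 2 higher of 22 (18 and 2 adjusted over the list alone) and a median of -0.52 (camera adjusted p = 0.00101; 0.179 with an estimated correlation), with HSPA5 at -1.28. Other miR-29 targets had 33 lower and 12 higher (33 and 13 adjusted over the list alone) and a median of -0.52 (camera adjusted p = 0.00101; 0.0971 with an estimated correlation). The p53 targets had 17 lower and 5 higher (17 and 5 adjusted over the list alone) and a median of -0.45 (camera adjusted p = 0.0138; 0.0929 with an estimated correlation), with TNFRSF10B at -1.84. Immediate early genes had 10 lower and 3 higher (10 and 3 adjusted over the list alone) and a median of -0.47 (camera adjusted p = 0.0318; 0.498 with an estimated correlation), with EGR1 at -1.80. Estrogen response genes had 22 lower and 15 higher (22 and 15 adjusted over the list alone) and a median of -0.25 (camera adjusted p = 0.0418; 0.38 with an estimated correlation), and 0.0535 without MCF-7 pre-miR-29b-1 replicate 1 or 0.0516 without MCF-7 anti-miR-29a replicate 3. Against the mean of 18 libraries, the list medians with anti-miR-29a were 0.07, -0.08 and 0.0009 in LCC9 and -0.02, 0.06 and 0.01 in MCF-7. With the precursors they were -0.37 to -0.25 in LCC9 and 0.14 to 0.46 in MCF-7, so the lower values in LCC9 were limited to these.

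Among the fixed genes, TFF1 (2.81), ERBB2 (0.91) and DNMT3B (0.74) were higher in LCC9. PIK3R1 (-2.32), CDK6 (-2.17), MCL1 (-1.23), TET2 (-1.10), GREB1 (-1.02), EGFR (-0.92), PGR (-0.65), ESR1 (-0.58), TET3 (-0.53), DNMT3A (-0.50), TDG (-0.24) and TET1 (-0.20) were lower, with limma adjusted p from 1.76e-15 (CDK6) to 0.0153 (TET1). Some of these depended on the transfection. With anti-miR-29a alone TDG was higher in LCC9 (0.74, limma adjusted p = 0.00204), with 71.2 against 42.4 FPKM, and ERBB2 (0.46, 0.143), PGR (-0.41, 0.127), TET3 (-0.61, 0.104), DNMT3A (-0.39, 0.0918) and TET1 (-0.12, 0.567) missed the threshold. With pre-miR-29a alone ESR1 (-0.17, 0.389) and TET1 (-0.21, 0.0501) missed it. TET1 was higher in LCC9 (0.18, 0.00325) once a GC and length trend was removed, and missed the threshold without LCC9 anti-miR-29a replicates 2 and 3 (-0.08, 0.134). ATP5MC1 (-0.12, 0.19) and ATP5IF1 (-0.05, 0.567) missed the threshold. Their difference between the lines also depended on the transfection, with limma interactions for pre-miR-29a of -0.80 (ATP5MC1) and -0.86 (ATP5IF1). The lines differed in 13498 genes, 7397 higher and 6101 lower in LCC9, of which 2150 and 1752 differed by at least 1 on the log2 scale.

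Interaction tests asked whether the response to a precursor differed between the lines. Single interferon-stimulated genes had the most negative interactions. OAS2 (-3.57, SE 0.31, limma adjusted p = 3.92e-06), IFIT3 (-3.32, 1.82e-05) and XAF1 (-3.08, 9.1e-07) rose with pre-miR-29a in MCF-7 and not in LCC9. In LCC9 OAS2 (-1.04, 0.00154) and IFIT3 (-0.76, 0.0231) fell, and XAF1 missed the threshold (-0.27, 0.175), with 21.1 ± 1.17 FPKM with anti-miR-29a and 17.6 ± 4.17 with pre-miR-29a. For pre-miR-29b-1 the lowest interactions were OAS2 (-3.66), XAF1 (-3.31) and KLHDC7B (-3.25). Interferon response genes had 36 lower interactions of 38 for pre-miR-29a (37 adjusted over the list alone), with a median of -1.81 (camera adjusted p = 2.28e-23; 0.0908 with an estimated correlation). For pre-miR-29b-1 there were also 36 (36 adjusted over the list alone), with a median of -1.90 (camera adjusted p = 5.12e-25; 0.057 with an estimated correlation). KLF2 (2.32 and 2.77), ANXA3 (1.98 for pre-miR-29a) and PKIA (2.06 for pre-miR-29b-1) had positive interactions. SLC2A3P1 (2.14, 0.0275) and RPL39P34 (2.48, 0.0484) are pseudogenes at the edge of the threshold. SLC2A3P1 missed it without LCC9 anti-miR-29a replicate 2 or 3, LCC9 pre-miR-29a replicate 2 or 3, MCF-7 anti-miR-29a replicate 2, or MCF-7 pre-miR-29a replicate 1 or 3 (0.0513 to 0.0751). RPL39P34 missed it without any 1 of the libraries other than LCC9 pre-miR-29b-1 replicate 1 and LCC9 anti-miR-29a replicate 3 (0.054 to 0.106).

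TDG fell further in LCC9 than in MCF-7 with pre-miR-29a (-1.54, SE 0.11, limma adjusted p = 1.06e-06) and with pre-miR-29b-1 (-1.40, 2.05e-06), as did DNMT3B (-1.06, 1.1e-05, and -1.21, 2.87e-06). The p53 targets rose further in LCC9: 10 were higher and 1 lower for pre-miR-29a (14 and 2 adjusted over the list alone), with a median of 0.44 (camera adjusted p = 4.25e-05; 0.00894 with an estimated correlation). For pre-miR-29b-1, 11 were higher and 2 lower (11 and 3 adjusted over the list alone), with a median of 0.46 (camera adjusted p = 0.00018; 0.0159 with an estimated correlation). FAS was higher by 1.21 (3.55e-05) and 0.83 (0.000656). Estrogen response genes had 18 lower and 1 higher for pre-miR-29a (21 and 1 adjusted over the list alone; median -0.43, camera adjusted p = 0.000309, 0.0908 with an estimated correlation). For pre-miR-29b-1, 20 were lower and 1 higher (24 and 1 adjusted over the list alone; median -0.52, camera adjusted p = 6.61e-07, 0.0203 with an estimated correlation). Cholesterol synthesis genes had 10 lower and 3 higher for pre-miR-29a (11 and 3 adjusted over the list alone; median -0.32, camera adjusted p = 0.0225, 0.229 with an estimated correlation). For pre-miR-29b-1, 10 were lower and 1 higher (12 and 2 adjusted over the list alone; median -0.36, camera adjusted p = 0.00142, 0.057 with an estimated correlation).

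For pre-miR-29a, oxidative phosphorylation genes had 14 lower interactions (15 adjusted over the list alone; median -0.48, camera adjusted p = 4.25e-05, 0.426 with an estimated correlation) and ribosomal protein genes 4 (1 adjusted over the list alone; median -0.53, camera adjusted p = 0.0017, 0.426 with an estimated correlation). For pre-miR-29b-1 these lists had 4 and 2 lower interactions (3 and none adjusted over the list alone), with medians of -0.28 and -0.47 (camera adjusted p = 0.0114 and 0.0203; 0.635 each with an estimated correlation). Both of the latter calls ended without LCC9 anti-miR-29a replicate 2 (0.117 and 0.113), and that of ribosomal proteins without MCF-7 anti-miR-29a replicate 2 (0.0833). Without LCC9 anti-miR-29a replicates 2 and 3 together, the oxidative phosphorylation median for pre-miR-29b-1 was 0.11. With a GC and length trend removed the oxidative phosphorylation medians were -0.23 for pre-miR-29a and -0.11 for pre-miR-29b-1. Those of ribosomal proteins were -0.25 and -0.14.

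Further list calls among the interactions sat near camera's threshold. Proliferation genes had 11 lower and 1 higher for pre-miR-29a (13 and 2 adjusted over the list alone; median -0.29, camera adjusted p = 0.0474, 0.426 with an estimated correlation) and 12 lower and 2 higher for pre-miR-29b-1 (16 and 2 adjusted over the list alone; median -0.25, camera adjusted p = 0.0204, 0.551 with an estimated correlation). The first call ended without LCC9 anti-miR-29a replicate 3 (0.0554), LCC9 pre-miR-29a replicate 3 (0.0548), MCF-7 anti-miR-29a replicate 1 or 3 (0.0636 and 0.116) or MCF-7 pre-miR-29a replicate 2 or 3 (0.11 and 0.061). The other ended without MCF-7 anti-miR-29a replicate 3 (0.0583). For pre-miR-29b-1, DNA methylation genes had 2 lower (2 adjusted over the list alone; median -0.25, camera adjusted p = 0.0337, 0.542 with an estimated correlation), a call lost without LCC9 pre-miR-29b-1 replicate 3 (0.0653), LCC9 anti-miR-29a replicate 1 (0.362) or MCF-7 anti-miR-29a replicate 3 (0.0516). Replication histones had 6 lower (7 adjusted over the list alone; median -0.79, camera adjusted p = 0.0243, 0.551 with an estimated correlation), lost without LCC9 or MCF-7 anti-miR-29a replicate 2 (0.0548 and 0.0762). Immediate early genes had 5 lower (5 and 1 higher adjusted over the list alone; median -0.46, camera adjusted p = 0.0444, 0.554 with an estimated correlation). Their call ended without LCC9 anti-miR-29a replicate 1 or 2 (0.118 and 0.0548), MCF-7 pre-miR-29b-1 replicate 1 (0.1) or MCF-7 anti-miR-29a replicate 2 (0.102).
The interactions counted 4334 genes past limma's threshold for pre-miR-29a, 1820 higher and 2514 lower, and 4074 for pre-miR-29b-1, 1786 and 2288. Without LCC9 anti-miR-29a replicate 1 the first count was 6506, and without replicates 2 and 3 the counts were 2246 and 2509. With median-ratio scaling 2223 were higher and 2049 lower for pre-miR-29a and 2117 and 1914 for pre-miR-29b-1, and with quantile normalization 2244 and 1806, and 2308 and 1671. Quantile normalization moved the median of all genes from -0.09 to 0.01 for pre-miR-29a and from -0.09 to 0.02 for pre-miR-29b-1.

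Sites for the miR-29 seed were then counted in 3′ UTRs, to ask whether genes with a site were lower where the microRNA was raised. Among genes lower with pre-miR-29a in MCF-7, 217 of 522 with a 3′ UTR (41.6%) had a site, against 23.0% of the others (odds ratio 2.38, Fisher's exact test, p = 3.97e-20). With pre-miR-29b-1 the shares were 36.1% and 22.3% (1.97, 1.06e-25). In LCC9 they were 29.3% and 22.0% with pre-miR-29a (1.47, 1.74e-15) and 32.4% and 21.6% with pre-miR-29b-1 (1.74, 4.44e-28; Fisher's exact test). Genes lower in LCC9 than in MCF-7, at matched transfection, also had a site more often, 29.9% against 20.3% (1.67, 1.22e-32), so such shares are not limited to comparisons in which the microRNA was raised. TDG carries 1 8mer at 104381932 to 104381939 on chromosome 12, DNMT3B 1 at 31396911 to 31396918 on chromosome 20 and MCL1 1 at 150548515 to 150548522 on chromosome 1 (GRCh37). TET2 carries 8mers at 106198272 to 106198279 and at 106199388 to 106199395 on chromosome 4. TET2 and MCL1 missed limma's threshold with either precursor in MCF-7, and XAF1, which rose there, carries a 7-base site. Genes with a site (2945) had a median log2 difference that differed from that of 7308 genes without the 6-base core of the site by -0.08 with pre-miR-29a in MCF-7, -0.06 in LCC9 and -0.10 with pre-miR-29b-1 in LCC9. None of 100 random 7-mers gave a difference as low in these comparisons, but 5, 10 and 5 of them did for MCF-7 without anti-miR-29a replicate 1 or 3 or pre-miR-29a replicate 2 (-0.09 each). In LCC9 the value for pre-miR-29a was -0.0121 without anti-miR-29a replicate 1, -0.095 without replicate 2 and -0.1922 with a GC and length trend removed, and that for pre-miR-29b-1 was -0.0423 without replicate 1 and -0.1783 with the trend removed, each below all 100. For pre-miR-29b-1 in MCF-7 the difference was -0.10, and 29 of 100 random 7-mers gave as low a value. With 8mer sites alone it was -0.15, and 2 of 100 did. Without anti-miR-29a replicate 2 it was -0.10, and with the trend removed -0.0602, each below all 100.

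Between precursors the difference was 0.01 in MCF-7 and 0.04 in LCC9, where 23 and 34 of 100 random 7-mers lay at or below it. Between the lines it was -0.29, with 7 of 100 at or below. With a GC and length trend removed it was -0.1081, below all 100, and with only 7-base sites of the m8 type -0.30, with 4 at or below. The interactions gave 0.02 for pre-miR-29a and -0.01 for pre-miR-29b-1, both below the lowest random 7-mer (0.07 and 0.03), and their sign changed with single libraries. Without LCC9 anti-miR-29a replicate 2 or 3 the first was -0.03 or -0.0009, and without LCC9 anti-miR-29a replicate 1 or LCC9 pre-miR-29b-1 replicate 3 the second was 0.05 or 0.001. With a GC and length trend removed they were -0.1381 and -0.1394, and without LCC9 anti-miR-29a replicates 2 and 3 together -0.1087 and -0.1203.

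**Figure D3:**
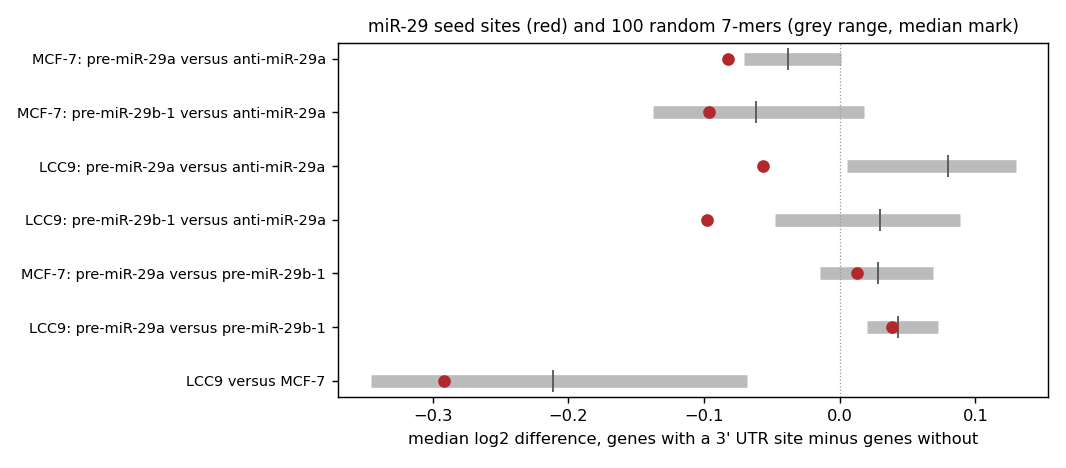
Median log2 difference of genes with a miR-29 site in the 3′ UTR minus that of genes without, for 7 comparisons (red points), with the range and median of 100 random 7-mers (grey). The point lies below the whole grey range for pre-miR-29a in both lines and for pre-miR-29b-1 in LCC9, and inside it for pre-miR-29b-1 in MCF-7.

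Luminal identity, mesenchymal and basal, BCL2 family, microRNA machinery and hypoxia genes passed camera's threshold in no comparison, and their lowest adjusted p were 0.117, 0.0685, 0.066, 0.112 and 0.119. The BCL2 family passed in MCF-7 with pre-miR-29b-1 without pre-miR-29b-1 replicate 3 (0.0443) or anti-miR-29a replicate 3 (0.0342), and luminal identity passed with pre-miR-29a without anti-miR-29a replicate 2 (0.00435). For mesenchymal and basal genes with pre-miR-29a the median was -0.16 in MCF-7 while the mean was 0.0017, and -0.01 in LCC9 with a mean of 0.11. Mitochondrial transcripts are listed at 0 in all 18 libraries for the 13 of 15 found in the table. Of 5 genes at miR-29 loci the table holds LINC-PINT, a long non-coding RNA, which was higher with each precursor (0.49 and 0.72 in MCF-7, 0.48 and 0.76 in LCC9, limma adjusted p from 0.000764 to 0.0447).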

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

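The 3 patterns weighed here were singled out because the interaction test found a different response to a precursor in LCC9 than in MCF-7, while the splits of the libraries are given for every comparison. The tests of transfected double-stranded RNA, of LCC9 anti-miR-29a as a group and of its replicates 2 and 3, and each test with the GC and length trend removed, were chosen after the data were seen.

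Interferon response genes rose with both precursors in MCF-7, while in LCC9 3 of 38 were higher and 18 lower with pre-miR-29a, and 6 higher and 4 lower with pre-miR-29b-1; camera's interaction calls were lost with an estimated correlation (adjusted p = 0.0908 and 0.057). A GC or length trend is argued against, since the median interaction over the list was -1.8082 with the trend removed (SE 0.181), against -1.8086 before. The SE of a list median, here and below, comes from the SD over list members and not from limma. It takes genes as independent and does not measure variation among cultures. A single deciding library is argued against as well, since at least 33 members stayed past the threshold without any 1 library. What stays open is that transfected double-stranded RNA, whatever its seed, could raise these genes. Without a neutral precursor that cannot be told apart from an effect of miR-29; the precursors differed from each other by -0.4193 over the list in MCF-7, and a biological difference between the lines is untested.

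More genes passed the threshold for pre-miR-29a against anti-miR-29a in LCC9 than in MCF-7. With the GC and length trend removed the LCC9 count was 3.47 times the MCF-7 count, which argues against that trend as the whole cause. Without LCC9 anti-miR-29a replicates 2 and 3 it was 2.55 times, but that cannot decide whether these libraries were the cause. The fit leaves 1 library in that group, takes its spread from the other groups, and counts its own deviation as a group difference. Fewer libraries alone could also lower a count. Nothing is concluded from this fit for pre-miR-29a or for pre-miR-29b-1. The 3 LCC9 anti-miR-29a libraries could differ as a group for a reason other than their transfection. The correlation of 0.7846 between the LCC9 precursor comparisons, which share them, leaves that open, as it leaves open a biological difference between the lines.

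Of the oxidative phosphorylation and ribosomal protein genes 37 of 49 and 16 of 24 were lower with pre-miR-29a in LCC9, but neither list's camera call held with an estimated correlation (adjusted p = 0.534 each). With the GC and length trend removed the oxidative phosphorylation median was -0.3727 (SE 0.043), against -0.524 before. It passed the bound of -0.35 set for keeping the pattern, by less than its SE. Without LCC9 anti-miR-29a replicates 2 and 3 the median was -0.1121 (SE 0.04). It passed the bound of -0.15 set for losing the pattern, also by less than its SE. The size of the median thus depended on these libraries, but the fit without them leaves 1 library in that group. The allowance of 1 SE at these bounds was added after the values were seen. With it, for this list neither the trend nor these libraries can be told apart from an effect of the transfection. The ribosomal protein median was -0.4257 with the trend removed, against -0.6035 before, and -0.20 without these libraries; no bound was set for that list, and no biological explanation was tested.

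Interaction counts were 4334 genes for pre-miR-29a and 4074 for pre-miR-29b-1. Among 100 splits of the libraries within lines, 3 gave as many as the first, the real split included, with 5563 in the highest other, and 1 as many as the second, with 3691 in the highest other. Both splits above 4334 genes kept the LCC9 groups and exchanged 6 or 4 of the 6 MCF-7 libraries, so they hold the LCC9 difference unchanged. For LCC9 against MCF-7, 1 of 100 splits gave as many as the 13498 found, and the highest other gave 10827. That split exchanged 1 of the 9 libraries of each line and so kept most of the grouping by line. With 3 against 3 libraries only 10 splits exist, too few to judge a count. For both MCF-7 precursor comparisons and LCC9 pre-miR-29a against anti-miR-29a, 1 split reached the real 1392, 4033 and 6881, with at most 2, 2 and 1 genes in any other. For LCC9 pre-miR-29b-1, 1 split reached 5963 and the highest other gave 580. Between precursors, 1 split reached 16 in MCF-7 (highest other 2) and 3 reached 2 in LCC9 (highest other 2).

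For pre-miR-29a, named genes whose log2 difference was more positive in LCC9 than in MCF-7 (limma interaction) were KLF2 2.32, SLC2A3P1 2.14, ANXA3 1.98, GPRC5A 1.67, PALM3 1.55, PKP1 1.53, KLF6 1.52, TP53INP1 1.49, TUBB3 1.36, FAS 1.21, HMOX1 1.04, GRIP1 1.02, ESR1 0.86, ERBB2 0.83, CAV1 0.77, ALG14 0.75 and CDK6 0.45. Interferon-related genes whose difference was more negative in LCC9 were OAS2 -3.57, IFIT3 -3.32, XAF1 -3.08, IFI44 -2.94, KLHDC7B -2.71, MX2 -2.53, CMPK2 -2.43, IFNB1 -2.37, PSMB9 -2.09 and IRF1 -1.35. Other genes whose difference was more negative in LCC9, many of which fell further there than in MCF-7, were PDXP -2.80, TIMM8B -2.78, CCDC167 -2.65, HPGD -2.37, PRMT6 -2.00, RCC2-AS1 -1.96, TBC1D7 -1.94, TAF11 -1.90, MYBL2 -1.85, SIAH2 -1.59, TDG -1.54, SERPINH1 -1.44, MYC -1.40, TFF1 -1.39, CXCL12 -1.36, INSIG1 -1.33, RPS29 -1.17, DNMT3B -1.06, PPIC -0.93, ATP5IF1 -0.86, ATP5MC3 -0.84, ATP5MC1 -0.80, PPM1D -0.69, ATF3 -0.57 and MCL1 -0.42.

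For pre-miR-29b-1, the genes whose difference was more positive in LCC9 were KLF2 2.77, RPL39P34 2.48, PKIA 2.06, PKP1 1.39, KLF6 1.37, PALM3 1.13, TUBB3 1.09, SEMA3D 1.03, PGM5 1.02, HMOX1 0.98, DDB2 0.83, FAS 0.83, CAV1 0.82 and ITGA6 0.76. Interferon-related genes whose difference was more negative in LCC9 were OAS2 -3.66, XAF1 -3.31, KLHDC7B -3.25, ISG15 -3.22, IFNL2 -3.22, IFIT3 -3.11, IFNB1 -2.63, CMPK2 -2.59, PSMB9 -2.46 and IRF1 -1.33. Other genes whose difference was more negative in LCC9 were IL24 -2.73, HPGD -2.71, CCDC167 -2.65, TIMM8B -2.52, VWC2L -2.44, MYBL2 -2.09, PRMT6 -1.90, TFF1 -1.83, RCC2-AS1 -1.82, SERPINH1 -1.70, TBC1D7 -1.56, MYC -1.54, SIAH2 -1.53, CXCL12 -1.51, TDG -1.40, INSIG1 -1.37, DNMT3B -1.21, RPS29 -0.84, VEGFA -0.83, PPIC -0.74, PPM1D -0.63, GREB1 -0.56 and MCL1 -0.34.

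Lists past camera's threshold with the preset correlation had the median interactions below. With an estimated correlation the calls held for p53 targets with pre-miR-29a (adjusted p = 0.00894) and for estrogen response (0.0203) and p53 targets (0.0159) with pre-miR-29b-1. The others were lost, with adjusted p from 0.0908 to 0.426 for pre-miR-29a and from 0.057 to 0.635 for pre-miR-29b-1. For pre-miR-29a they were interferon response -1.81, ribosomal proteins -0.53, oxidative phosphorylation -0.48, p53 targets 0.44, estrogen response -0.43, cholesterol synthesis -0.32 and proliferation -0.29. For pre-miR-29b-1 they were interferon response -1.90, replication histones -0.79, estrogen response -0.52, ribosomal proteins -0.47, p53 targets 0.46, immediate early -0.46, cholesterol synthesis -0.36, oxidative phosphorylation -0.28, DNA methylation -0.25 and proliferation -0.25.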

How the results depend on the processing

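Tests with the GC and length trend removed, without pairs of libraries, and of the lists under other scalings or without each library were chosen after the data were seen. Among named genes 4661 results kept direction and side of the threshold, 52 gained the call, 111 lost it and 7 reversed. For lists these numbers were 2949, 106, 163 and 2. Of the counts of genes 162 stayed within 1.5 times and 38 moved. No called list changed direction under another scaling. With 3 libraries per group, genes that change by 0.5 on the log2 scale are often missed. At a given FPKM, a short transcript rests on fewer reads than a long one.

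Requiring a log2 size of at least 1 left 120 and 427 genes for the miR-29a and the miR-29b-1 precursor in MCF-7, 755 and 573 in LCC9, 6 between precursors in MCF-7, 3902 between lines, and 787 and 788 interactions, by construction of a stricter threshold. Fitting only the groups compared gave 491 and 1472 genes for the miR-29a and the miR-29b-1 precursor in MCF-7, and 653 between precursors in LCC9. With the GC and length trend removed pre-miR-29a in MCF-7 gave 2211 genes, 2343 with the replicate block too, and precursors in LCC9 differed in 5. Without LCC9 anti-miR-29a replicates 2 and 3 there were 3549 and 3486 genes for the LCC9 comparisons and 2246 and 2509 interactions. The 1 library left was assumed to vary like the other groups. Without MCF-7 anti-miR-29a replicate 2 and MCF-7 pre-miR-29b-1 replicate 1, pre-miR-29b-1 gave 1729 genes and precursors in MCF-7 differed in 9. Between precursors in MCF-7 the count was 1 with 0.1 added before the log2, 44 with 5 added, 43 with no filter and 3 with a filter of 5 FPKM. In LCC9 it was 15 with 5 added and 23 with no filter. The cause was not tested.

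With each library left out in turn, the counts ran from 749 to 1305 for pre-miR-29a and from 2322 to 4474 for pre-miR-29b-1 in MCF-7, from 3 to 14 between precursors in MCF-7, from 2 to 10 in LCC9, and from 3329 to 6506 for the interaction of pre-miR-29a. The other counts stayed within 1.5 times. The cause was not tested.

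The labels do not say that replicate numbers pair the samples. Same-numbered libraries of a line correlated at -0.134 to 0.334 in their deviations, and 12 of 18 libraries correlated best with their own number. A random match would give fewer, since most candidate libraries carried another number. Pairing is thus neither shown nor excluded. With a replicate block the counts were 1652 and 5053 for the miR-29a and the miR-29b-1 precursor in MCF-7, 7494 and 6623 in LCC9, 13 and 4 between precursors, 13599 between lines, and 4995 and 4821 interactions.

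These values reversed. For pre-miR-29a in LCC9, GREB1 was -0.2323 with the trend removed (limma adjusted p = 0.0107; 0.00425 with the replicate block) and -0.3739 without anti-miR-29a replicates 2 and 3 (0.012); its adjusted p was 0.943 with all libraries. For pre-miR-29b-1 in LCC9 PIK3R1 was -0.7413 without the same libraries (0.00571). Between lines TDG was 0.7399 among anti-miR-29a samples alone, and TET1 was 0.1843 with the trend removed, with or without the replicate block. For the interaction of pre-miR-29b-1 without LCC9 anti-miR-29a replicates 2 and 3, the medians were 0.1138 for oxidative phosphorylation (camera adjusted p = 0.11) and -0.0649 for ribosomal proteins (0.573, camera's direction reversed). For seed sites the interaction of pre-miR-29b-1 was 0.0061 with 8mer sites alone and ran from -0.0578 to 0.0536 without 1 library. That of pre-miR-29a was -0.1381 with the trend removed and -0.1087 without replicates 2 and 3 (-0.1394 and -0.1203 for pre-miR-29b-1), and ran from -0.0308 to 0.0746 without 1 library. The cause was not tested.

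Further list calls ended, these among them (camera adjusted p). Median-ratio scaling ended growth factor receptors (0.0517) and p53 targets (0.0777) for pre-miR-29a in MCF-7, matrix targets for pre-miR-29b-1 in LCC9 (0.0601) and proliferation for the interaction of pre-miR-29a (0.084). Quantile normalization ended estrogen response (0.0632) and cholesterol synthesis (0.0775) for pre-miR-29a in LCC9, immediate early genes for pre-miR-29b-1 in LCC9 (0.0533), proliferation for both interactions (0.316 and 0.195) and oxidative phosphorylation for that of pre-miR-29b-1 (0.065). Leaving out LCC9 anti-miR-29a replicates 2 and 3 ended interferon response (0.11) and cholesterol synthesis (0.109) for pre-miR-29a in LCC9, ribosomal proteins (0.0546) and immediate early genes (0.145) for pre-miR-29b-1, and oxidative phosphorylation (0.506) and ribosomal proteins (0.491) for the interaction of pre-miR-29a. With the trend removed DNMT3A passed limma's threshold in LCC9 with pre-miR-29a (-0.50, 0.00469) and pre-miR-29b-1 (-0.51, 0.0047). Between lines ESR1 lost its call among pre-miR-29a samples alone (-0.17, 0.389), and TET1, DNMT3A, TET3, PGR and ERBB2 lost theirs among anti-miR-29a samples alone. The cause was not tested.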

Other observations

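No test in this part was chosen after its result was seen, and each value comes from a list fixed beforehand. Markers of other cell types stayed low in these cultures. Of 13 leukocyte markers 1 passed the filter and the highest mean was 3.17 FPKM, of 13 fibroblast markers 4 passed (highest mean 8.09 FPKM), and of 8 endothelial markers 1 passed (highest mean 2.92 FPKM). LINC-PINT, the 1 tested gene of the miR-29 loci, had a mean of 5.9 FPKM over the 18 libraries and was lower in LCC9 than in MCF-7 (-1.06, limma adjusted p = 1.12e-08).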
